A study of Homo sapiens with 12 samples.

How the data were processed

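Total RNA of T47D cells was measured on Illumina bead arrays with 1 colour (Cy3). Arrays were grouped by the submitters' labels into 4 groups of 3: si-Luc and si-CypB cells, each untreated or given prolactin (PRL). The deposited values were on a log2-like scale, with array medians of 6.82 to 6.83, and had been made by the authors with lumi 1.5.11, per the submitters' processing notes. The transform, its log base, the background correction and the normalisation between arrays are not given in the sources used here. Differences are therefore called log2 differences on the scale of the authors' deposited values. The 12 arrays had nearly the same distribution, with a largest difference of 0.544 between arrays at the same rank. Most dim probes lay just under 7, and the 0.1 percentile of the arrays, called the floor here, lay between 6.57 and 6.62. A level near this floor compresses the difference of a weakly expressed gene, so such differences understate the change.

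All 48701 probes were tested. A platform annotation table gave 1 gene symbol for 23687 probes, several for 35 and none for 24979. Of the probes with 1 symbol, 23651 matched the RefSeq gene table of GRCh38.p14 by Entrez identifier, and 0 symbols changed. A gene was represented by its leading probe, which is the probe with the highest mean over the 12 arrays, and 18774 genes had one. No name was taken from a probe with several symbols.

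The deposited log2 values were used without further normalisation. limma 3.58.1 in R 4.3.3 fitted a mean for each of the 4 groups over all 12 arrays, with 8 residual and 3.36 prior degrees of freedom, and eBayes gave moderated two-sided tests. The 7 contrasts were the line difference untreated, the line difference with PRL, PRL in si-Luc, PRL in si-CypB, the difference between both PRL effects (the interaction), and the averages of the line differences and of the PRL effects. P-values were adjusted by the Benjamini-Hochberg method over all probes within a contrast, and a probe or gene was called at an adjusted p below 0.05. Every adjusted p of a gene comes from this limma fit. Groups are given as mean ± SD with n = 3 arrays, and SE is the standard error of the fitted difference.

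The contrasts, the tests, the alternatives listed in advance, the gene lists and the rule for named genes were fixed before the data were examined. Named genes were PPIB in every contrast. Per contrast, the rule also took up to 10 genes with the largest rise and 10 with the largest fall among called genes whose highest group mean exceeded the median of the table, 6.83, and whose 3 values in one group all lay beyond the 3 of the other. The last condition did not apply to the contrasts of 4 groups. From each gene list it took up to 4 called members with the smallest adjusted p, or 1 member with the largest statistic where no member was called. CISH, SOCS2, SOCS3 and MYC were named in the PRL contrasts whatever their p. The text prints a part of these genes. One result under this rule is not reported here.

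The 19 gene lists were cyclophilins, STAT5 and prolactin targets, the prolactin receptor and JAK-STAT machinery, immediate early and MAPK feedback genes, endoplasmic reticulum chaperones with the unfolded protein response, collagen folding partners of cyclophilin B, estrogen response, cell cycle, luminal markers, basal and mesenchymal markers, immune with endothelial and fibroblast markers, interferon-stimulated genes, matrix proteases with adhesion genes, apoptosis regulators, p53 targets, hypoxia with glycolysis, cholesterol synthesis with uptake, oxidative stress, and hormone and growth factor genes. limma's camera compared each list with the other genes using a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. List p-values were adjusted over the 19 lists of a contrast. limma's fry tested whether a list's genes moved on balance one way, without comparing them with other genes, and its mixed test whether they changed in either direction. By fry's one-way test, 13 lists passed for the line difference untreated, 15 with PRL, 1 for PRL in si-Luc, 1 for PRL in si-CypB and 0 for the interaction. In lists that did not pass camera, the median, the mean and the direction of the test differed in sign in some contrasts; no list that passed did so.

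The fit was tested on simulated data over 48701 probes, with a pooled spread per probe taken from the real fit and equal on all 12 arrays. For the line difference untreated, 44 of 50 probes changed by 0.25 were recovered, 48 of 50 at 0.5, 50 of 50 at 1 and 50 of 50 at 2, with 12 false calls. For PRL in si-Luc, 46, 47, 50 and 50 of 50 were recovered at the same sizes, with 14 false calls. A list shifted by 0.3 was found, and 0 other lists were called. The simulated noise was independent between probes, so the list result cannot show how camera's preset correlation serves correlated genes. Changed probes were drawn from all probes, dim ones included, so the recovery is an average over dim and bright probes. The real groups differed in spread and some arrays stood apart from theirs, so the recovery may overstate what the real contrasts detect.

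Alternatives fixed in advance were an intensity trend with robust hyperparameters, limma's treat against a fold of 1.2, only the groups compared in the fit, array weights, quantile normalisation again, centring on the median, only probes brighter than the median of all probes, only leading probes, the replicate number as a block, and each array left out in turn. After the data were seen, fits without the arrays that stood apart from their groups, and without 12 probes that held values at least 0.1 below the floor, were added, as was a test of the cyclophilin list without PPIB. Between untreated and PRL arrays of si-CypB cells, deviations of arrays with the same replicate number correlated at 0.125, 0.406 and 0.466, so the numbers were taken to pair these arrays. By these values the pairing is incomplete, since untreated replicate 1 correlated best with PRL replicate 3. In no other pair of groups did all 3 exceed 0.1. Between untreated and PRL arrays of si-Luc cells r was 0.294, 0.266 and 0.024, although each number correlated best with its own. The number of arrays limits the precision. Nothing in the sources used here says that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Detection p-values were not used here.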

Results

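Gene expression was measured in T47D cells, an established luminal breast cancer line that carries receptors for estrogen, progesterone and prolactin. A lentiviral vector gave stable lines with a small interfering RNA against luciferase (si-Luc, the control) or against cyclophilin B (si-CypB). Cyclophilin B, the product of PPIB, is a peptidyl-prolyl isomerase of the endoplasmic reticulum that also binds the pituitary hormone prolactin (PRL). Cells were grown, growth-arrested for 24 hours and left untreated or given PRL at 100 ng/ml for 2 hours. Each of the 4 groups had 3 arrays, and each array held 48701 probes standing for 18774 named genes. Correlations between arrays of one group ran from 0.989 to 0.998 across probes, and no pair of arrays held identical values.

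PPIB, the targeted gene, was read by the single probe ILMN_1711745. It stood at 12.58 ± 0.09 (SD, n = 3) in si-Luc cells and at 8.86 ± 0.43 in si-CypB cells, and with PRL at 12.51 ± 0.04 and 8.78 ± 0.28. The line difference was -3.71 log2 (SE 0.18, adjusted p = 4.43e-07) untreated and -3.73 (adjusted p = 4.75e-07) with PRL. The si-CypB arrays read 9.31, 8.46 and 8.82 untreated, each far below every si-Luc array. PRL itself left PPIB within the spread of the arrays, by -0.07 in si-Luc (adjusted p = 0.967) and -0.09 in si-CypB (adjusted p = 0.922).

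**Figure D1:**
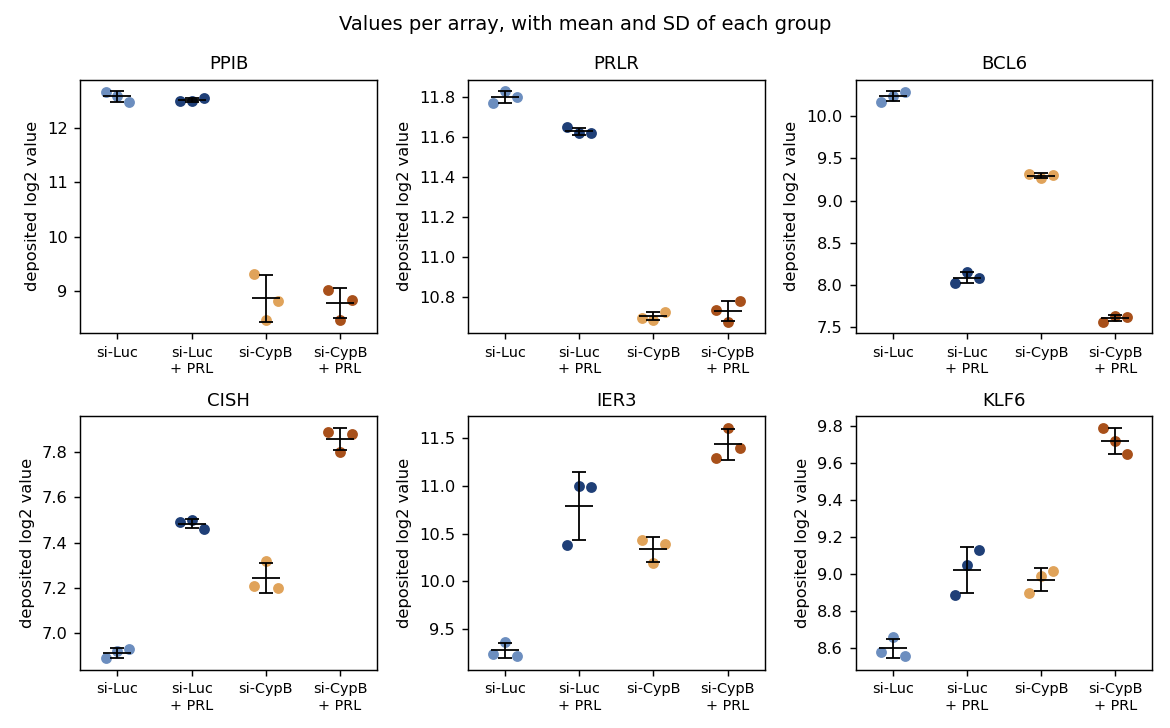
Log2 values of PPIB, PRLR, BCL6, CISH, IER3 and KLF6 on each of the 12 arrays, with the group mean and SD (n = 3). PPIB stands near 12.58 in si-Luc and 8.86 in si-CypB cells, and BCL6 falls from 10.23 to 8.09 with PRL in si-Luc cells.

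The first comparison asked what differed between the si-CypB and si-Luc lines without PRL. The most strongly raised genes in si-CypB cells were a pair of short noncoding RNAs, SNAR-A1 (3.12 log2, SE 0.31, adjusted p = 6.43e-05) and BCYRN1 (3.07, SE 0.28, adjusted p = 3.56e-05). SNAR-A1 went from 10.19 ± 0.27 to 13.30 ± 0.23, and belongs to a family of near-identical copies, so its identity is uncertain. PRLR, the receptor for prolactin, fell by 1.09 (SE 0.03, adjusted p = 1.13e-08), from 11.80 to 10.71. ESR1, the estrogen receptor, fell by 0.80, and HSPA5, the main chaperone of the endoplasmic reticulum, fell by 1.04. FASN, the fatty acid synthase, rose by 1.09, from 12.41 to 13.50.

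Other strong rises were SPINK4, a protease inhibitor (2.51), VCX (2.29), MMD (1.64), the metallothionein MT2A (1.52), SOWAHA (1.49), the mitochondrial carrier UCP2 (1.45), CLIC6 (1.42) and the imprinted gene PEG10 (1.41). VCX has near-identical copies and is uncertain, although 3 of its 4 other probes were called in the same direction. The strongest falls after PPIB were STMN3, of the stathmin family (-2.42), TXNIP, an inhibitor of thioredoxin (-2.12), the adhesion molecule CADM1 (-2.05), ASS1 of arginine synthesis (-2.02), the heparan sulfate proteoglycan GPC6 (-1.97), the caveolar coat protein CAVIN1 (-1.84), the mitochondrial protein CHCHD10 (-1.78), PAPSS2 of sulfate activation (-1.76) and the heparan sulfatase SULF1 (-1.69). A second GPC6 probe differed by -0.25. UCP2 rested partly on si-CypB replicate 2, which read 11.19 against 9.77 and 9.80 on its partners, and rose by 0.98 without it (adjusted p = 4.57e-05). In all, 4224 probes were called, 1914 higher and 2310 lower, and they covered 1406 genes higher and 1849 lower.

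Of 27 measured genes for cholesterol synthesis and uptake, 15 rose and 0 fell (16 rose and 1 fell adjusted over the list alone), with a median of 0.40 and a camera adjusted p of 1.42e-08. FASN, ELOVL6 (0.67), INSIG1 (0.94) and SC5D (0.71) had the smallest adjusted p in the list. Genes of hypoxia and glycolysis went the other way, with 17 of 32 lower and 2 higher (20 and 2 adjusted over the list alone; adjusted p = 4.51e-08). NDRG1 (-1.02), BNIP3L (-0.63), HK2 (-0.48) and the glucose transporter SLC2A1 (-0.47) were among them. Collagen folding partners of cyclophilin B fell in 9 of 16 cases, and 0 rose (10 and 0 adjusted over the list alone; adjusted p = 2.95e-05). They included CRTAP (-0.48) and P3H1 (-0.29), which form the prolyl 3-hydroxylase complex with cyclophilin B, and the collagen chaperone SERPINH1 (-0.76).

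Of 29 measured genes of the prolactin receptor and JAK-STAT machinery, 8 fell and 0 rose (11 fell and 2 rose adjusted over the list alone; adjusted p = 0.00458). PRLR, VAV2 (-0.26), PIAS2 (-0.26) and STAT6 (-0.20) had the smallest adjusted p among them. Luminal markers fell in 9 of 25 cases and rose in 1 (13 and 3 adjusted over the list alone; adjusted p = 0.00255), with KRT18 at -0.38 and GATA3 at -0.27. Basal and mesenchymal markers did not move the opposite way, since 7 of 22 fell and 0 rose (8 and 1 adjusted over the list alone; adjusted p = 0.00244), among them S100A4 (-1.48), CDH3 (-1.29), ACTA2 (-1.24) and CD44 (-0.57). These calls, and those of the cholesterol, hypoxia and collagen lists, held with an estimated correlation. The luminal list shared 9 genes with other lists, the collagen list 3 and the hypoxia list 3.

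Among cell cycle genes, 23 of 54 rose and 3 fell (26 and 4 adjusted over the list alone; adjusted p = 1.66e-07, and adjusted p = 0.0527 with an estimated correlation). The mitotic kinases AURKA (0.64) and BUB1 (0.59), the securin PTTG1 (0.64) and the kinetochore motor CENPE (0.47) had the smallest adjusted p. Of 36 endoplasmic reticulum chaperones and unfolded protein response genes, 12 fell and 1 rose (16 and 2 adjusted over the list alone; adjusted p = 0.000198, and adjusted p = 0.101 with an estimated correlation). Besides HSPA5 these were PDIA5 (-0.47) and PDIA6 (-0.43), while MANF rose by 0.59. Interferon-stimulated genes fell in 12 of 48 cases and rose in 3 (18 and 5 adjusted over the list alone). Camera gave them an adjusted p = 0.00976, and adjusted p = 0.528 with an estimated correlation. IFI35 (-0.66) and EIF2AK2 (-0.38) were among the members with the smallest adjusted p. Estrogen response genes fell in 13 of 41 cases and rose in 7 (16 and 8 adjusted over the list alone; adjusted p = 0.0439, and adjusted p = 0.0707 with an estimated correlation or 0.124 over bright probes), with CXCL12 at -1.22 and PRSS23 at -0.70. That list shared 11 genes with other lists. Of 15 cyclophilins 3 fell, PPIB itself, PPIC (-0.61) and PPIL1 (-0.31), and 0 rose (3 and 0 adjusted over the list alone; adjusted p = 0.0104, and adjusted p = 0.0521 with an estimated correlation). The fall of PPIB was set by the design, and without it, in a test chosen after the data were seen, the other 14 cyclophilins did not pass (median -0.07, adjusted p = 0.0587).

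The remaining 8 lists did not pass. Of 22 STAT5 and prolactin targets 2 rose and 3 fell (2 and 4 adjusted over the list alone; adjusted p = 0.898), with PIP higher by 1.24, CISH by 0.33, BCL6 at -0.94 and ELF5 at -0.70. Of 35 immediate early genes 4 rose and 7 fell (5 and 7 adjusted over the list alone; adjusted p = 0.926), with IER3 at 1.06 and DUSP4 at -0.98. Apoptosis regulators rose in 4 of 35 cases and fell in 5 (8 and 6 adjusted over the list alone; adjusted p = 0.745), with BID at -0.71 and BCL2L2 at 0.52. For these lists the median and camera's direction were upward and the mean downward. Matrix proteases and adhesion genes rose in 1 of 43 cases and fell in 7 (1 and 8 adjusted over the list alone; adjusted p = 0.061), with the protease inhibitor TIMP2 at -0.71. That list passed over bright probes (adjusted p = 0.0345) and without both arrays that stood apart from their groups, si-CypB replicate 2 and si-Luc PRL replicate 1 (adjusted p = 0.0178), a fit chosen after the data were seen. Hormone and growth factor genes rose in 4 of 44 cases and fell in 7 (4 and 8 adjusted over the list alone; adjusted p = 0.061, and adjusted p = 0.0455 without both arrays), with BMP4 at -0.95. Of 31 oxidative stress genes 5 rose and 8 fell (6 and 9 adjusted over the list alone; adjusted p = 0.779), with the catalase gene CAT at -0.80. Of 29 p53 targets 4 rose and 3 fell (4 and 4 adjusted over the list alone; adjusted p = 0.659), with BTG1 at 0.60. Among 21 immune, endothelial and fibroblast markers, which a pure epithelial line should lack, COL1A1 alone was called, at 0.19 (1 and 0 adjusted over the list alone; adjusted p = 0.386), and 11 of the 21 had means below the median of the table.

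One array of the si-CypB group, replicate 2, stood apart in this comparison. Among brighter probes, 71 lay over 1 log2 unit from the mean of the other si-CypB replicates, against 0 for every si-Luc array. The labels name 1 line per vector, so an effect of the silenced gene and a difference between these lines cannot be separated.

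**Figure D2:**
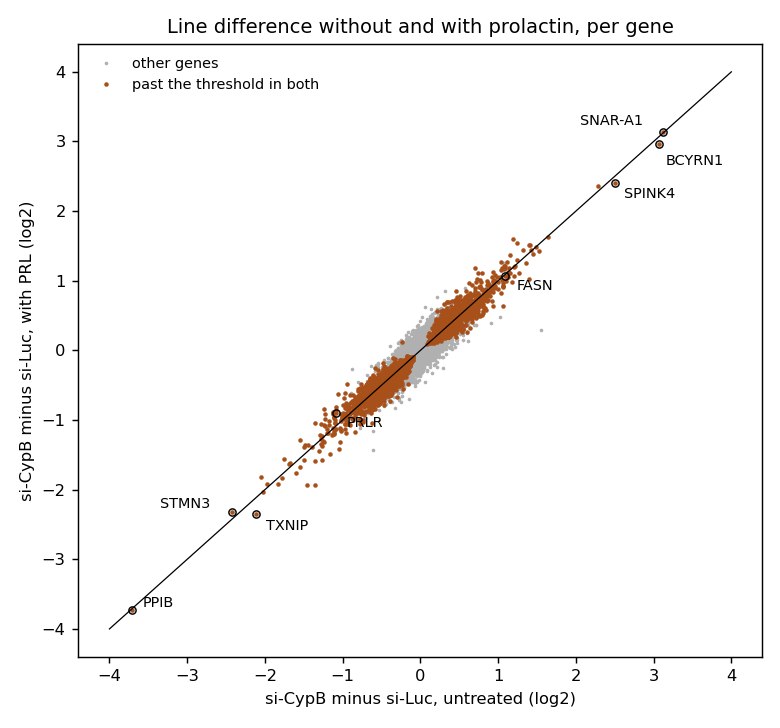
Each point is a gene's log2 difference between si-CypB and si-Luc cells, untreated on the horizontal and with PRL on the vertical axis, with the line of equality and genes called in both comparisons coloured. PPIB lies at -3.71 and -3.73, and SNAR-A1 at 3.12 and 3.14.

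The second comparison set the same lines against each other after PRL. SNAR-A1 (3.14), BCYRN1 (2.97), SPINK4 (2.40) and VCX (2.36) were again highest in si-CypB cells, followed by MMD (1.63), NIPSNAP1 (1.60), PIP, a secreted protein induced by prolactin and androgens (1.54), and SAR1B of vesicle budding (1.51). TXNIP (-2.35), STMN3 (-2.31), ASS1 (-2.03), NIBAN1 (-1.94), LAMP3 (-1.93), CAVIN1 (-1.93) and GPC6 (-1.92) were lowest after PPIB. PRLR was lower by -0.90, its relative GHR, the growth hormone receptor, by -0.85, and the cell cycle inhibitor CDKN1A by -1.42. On si-Luc PRL replicate 1, which stood apart, NIBAN1 read 9.38 against 10.98 and 10.72 on its partners. LAMP3 read 8.19 there against 9.9 and 9.46, and CDKN1A 10.91 against 12.15 and 11.84. The sizes of these differences therefore depend on that array. limma called 4177 probes, 1970 higher and 2207 lower.

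Across gene lists, 18 of 27 cholesterol genes rose and 0 fell (21 and 0 adjusted over the list alone; adjusted p = 2.42e-12), with MSMO1 at 1.19 and SQLE at 0.85. Cell cycle genes rose in 24 of 54 cases and fell in 1 (32 and 4 adjusted over the list alone; adjusted p = 2.91e-11), with PTTG1 at 0.79 and KIF20A at 0.67. Of the JAK-STAT machinery 12 of 29 genes fell and 0 rose (15 and 1 adjusted over the list alone; adjusted p = 0.000393), with STAT5A at -0.27 and PTPN2 at -0.22. Collagen folding partners fell in 8 of 16 cases and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.000393), with PLOD1 at -0.79. Luminal markers fell in 9 of 25 cases and rose in 1 (12 and 4 adjusted over the list alone; adjusted p = 0.00897), with MUC1 at -0.57, and basal markers fell in 6 of 22 and rose in 0 (8 and 0 adjusted over the list alone; adjusted p = 0.00133). These 6 calls held with an estimated correlation. The chaperone list, with 15 of 36 lower and 1 higher (18 and 1 adjusted over the list alone), had HSPA5 at -1.32 and CANX at -0.59, and its adjusted p was 3.02e-05, or adjusted p = 0.0825 with an estimated correlation. Hypoxia genes fell in 13 of 32 cases and rose in 2 (17 and 3 adjusted over the list alone; adjusted p = 0.00011, and adjusted p = 0.0825 with an estimated correlation). Interferon-stimulated genes fell in 12 of 48 cases and rose in 1 (14 and 2 adjusted over the list alone; adjusted p = 0.00771, and adjusted p = 0.47 with an estimated correlation). Without both arrays that stood apart the interferon call was lost (11 fell, 8 rose, adjusted p = 0.296). si-Luc PRL replicate 1 had a mean of 8.26 over that list, against 7.87 to 8.06 on the si-CypB PRL arrays. Of 15 cyclophilins PPIB and PPIC (-0.42) fell and 0 rose (2 and 0 adjusted over the list alone; adjusted p = 0.0432, and adjusted p = 0.0825 with an estimated correlation). Their call was also lost without PPIB (median -0.06, adjusted p = 0.15), without both arrays that stood apart (adjusted p = 0.0725) and over bright probes (adjusted p = 0.0828).

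**Figure D3:**
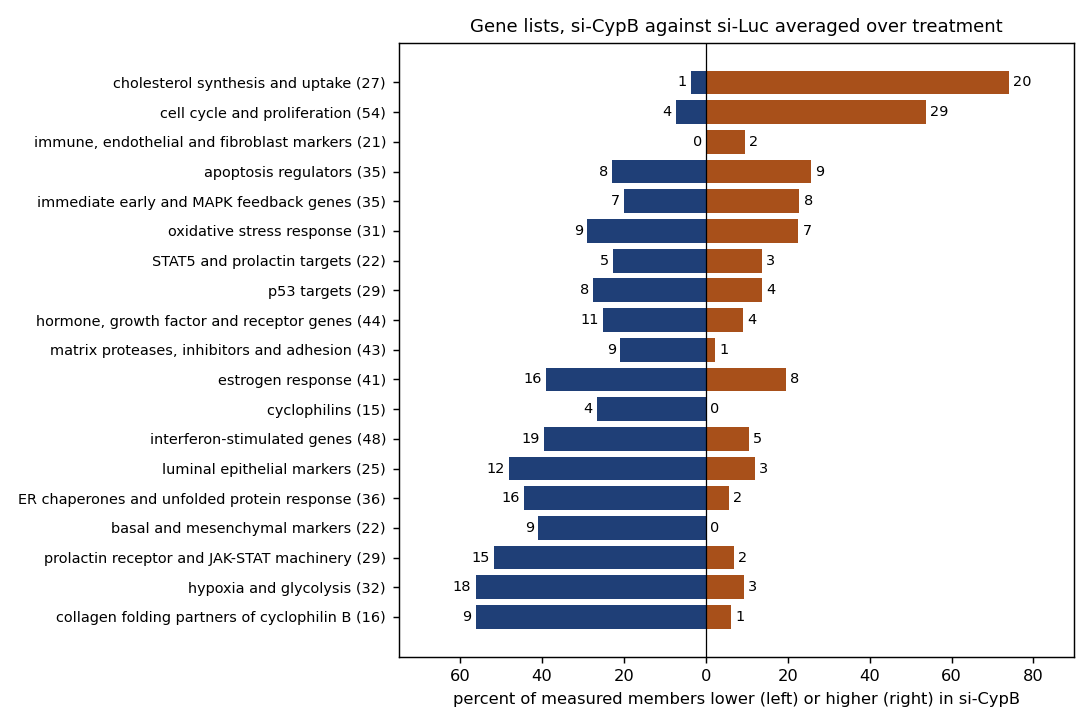
Percent of each list's measured members called lower (left) or higher (right) in si-CypB than in si-Luc cells, averaged over both treatments, with the number of members beside each bar. Cholesterol genes lie to the right, with 20 of 27 higher, and hypoxia genes to the left, with 18 of 32 lower.

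The line difference was nearly the same without and with PRL. Across 18774 genes the differences correlated at r = 0.925 (Spearman's coefficient 0.726, covariance 0.0489), with no array shared between them and with r between 0.869 and 0.925 when single arrays were left out. Genes are not independent replicates, so this r describes the arrays. Of the genes called, 1049 were higher in both, against 112 from independent lists of these sizes, and 1398 were lower in both, against 179. One gene was called in opposite directions, NDUFB8 of respiratory complex I (-0.23 untreated, 0.12 with PRL), and is named because of its values. Averaged over both treatments, 6566 probes were called, 3126 higher and 3440 lower. Of the lists, 20 of 27 cholesterol genes rose and 1 fell (22 and 1 adjusted over the list alone; adjusted p = 1.23e-10), 29 of 54 cell cycle genes rose and 4 fell (34 and 4 adjusted over the list alone; adjusted p = 1.23e-09), and 18 of 32 hypoxia genes fell and 3 rose (22 and 3 adjusted over the list alone; adjusted p = 1.19e-06), and all these held with an estimated correlation. Of the 19 lists 10 passed on this average, and 7 did with an estimated correlation. Cyclophilins, 1 of the 10, did not pass without PPIB (adjusted p = 0.0656).

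The third comparison asked what 2 hours of PRL did in control cells. BCL6, a transcriptional repressor that STAT5 is known to silence, fell by 2.14 (SE 0.04, adjusted p = 1.36e-10), from 10.23 to 8.09. CISH, a feedback inhibitor and classical STAT5 target, rose by 0.57 (adjusted p = 6.79e-05), from 6.91 to 7.49, close to the floor. IER3, an immediate early gene, rose by 1.51 (SE 0.14, adjusted p = 0.00234), from 9.28 to 10.79. KLF6, another early gene, rose by 0.42 (adjusted p = 0.0465). MYC read 9.06 and 9.57, a difference of 0.51 that did not pass (adjusted p = 0.332), and the feedback inhibitors SOCS2 (0.10, adjusted p = 0.503) and SOCS3 (0.02, adjusted p = 0.941) lay near the floor.

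limma called 16 probes, 10 higher and 6 lower, for 12 genes. YAP1, the Hippo pathway effector, was among those higher (0.24), and ALDH7A1 (-0.42), LRIG3 (-0.38), TMEM230 (-0.29) and HPF1 (-0.22) were among those lower. Of the 16 probes, 5 held values below the floor on some arrays, among them BCL3 (0.81) and ZSCAN26 (-1.38), which makes those differences uncertain. Without the probes of that kind 3 were called, a fit chosen after the data were seen, and BCL6, CISH and IER3 passed in it. Replicate 1 of the si-Luc PRL arrays stood apart, with 14 brighter probes over 1 log2 unit from the mean of its partners. Without it 137 probes were called, and MYC was among them (0.67, adjusted p = 0.0291). Without any single one of the other 5 arrays compared 7 probes were called, and KLF6, YAP1, ALDH7A1, LRIG3, TMEM230, HPF1 and BCL3 lost their calls, with a highest adjusted p between 0.264 and 0.357.

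Immediate early and MAPK feedback genes rose as a group. Of 35 measured, 2 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.07 and an adjusted p of 8.51e-09, a call that held with an estimated correlation. STAT5 and prolactin targets rose in 1 of 22 cases and fell in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0458, and adjusted p = 0.27 with an estimated correlation). In 4 more lists camera passed with 0 members called, and 0 adjusted over the list alone. Upward shifts were found for p53 targets (median 0.09, adjusted p = 0.00235, and adjusted p = 0.27 with an estimated correlation) and apoptosis regulators (median 0.03, adjusted p = 0.0458, and adjusted p = 0.36 with an estimated correlation). Downward shifts were found for cell cycle genes (median -0.07, adjusted p = 0.00235, and adjusted p = 0.36 with an estimated correlation) and interferon-stimulated genes (median -0.06, adjusted p = 0.00093, and adjusted p = 0.572 with an estimated correlation). Replicate 1 of the si-Luc PRL arrays, which stood apart, showed little or none of the STAT5, p53, cell cycle and interferon shifts and less of that in apoptosis regulators. Its mean over STAT5 targets was 8.26, within the untreated 8.26 to 8.28, against 8.31 and 8.29 on its partners. Its mean over apoptosis regulators was 7.85, against 7.90 on both partners and 7.82 to 7.84 untreated. Its mean over p53 targets was 8.37, within the untreated 8.36 to 8.43, against 8.66 and 8.58 on its partners. Its mean over cell cycle genes was 9.01, against 8.91 and 8.95 on its partners and 9.01 to 9.02 untreated. Its mean over interferon-stimulated genes was 8.26, above the untreated 8.20 to 8.23, while both partners read 8.10 or lower. Without both arrays that stood apart the medians were 0.14 for p53 targets, with 9 members higher, and -0.14 for interferon-stimulated genes, with 6 lower and 1 higher.

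The fourth comparison asked the same of si-CypB cells. BCL6 fell by 1.69 (adjusted p = 2.03e-09), from 9.30 to 7.61, CISH rose by 0.61 (adjusted p = 3.13e-05), IER3 by 1.10 (adjusted p = 0.0131) and KLF6 by 0.75 (adjusted p = 0.000511), the latter by both of its probes. Further rises were NABP1, a DNA-binding protein of damage repair (0.76), the transcription factor CEBPD (0.66), the prostaglandin receptor PTGER4 (0.61), TNFRSF12A (0.59), UBALD2 (0.53) and EGR1 (0.32). SNORD68 (-0.42), SNX16 (-0.37), the replication factor RFC4 (-0.36) and ACP1 (-0.34) fell. SOCS2 (0.03, adjusted p = 0.838), SOCS3 (-0.01, adjusted p = 0.922) and MYC (0.50, adjusted p = 0.179) did not pass.

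limma called 125 probes, 92 higher and 33 lower, and 6 of them held values below the floor. Without si-CypB replicate 2, the array that stood apart, 1934 were called, and without any other single array compared between 40 and 59. With only the groups compared in the fit, fewer probes were called here than for PRL in si-Luc. The counts therefore do not show a broader response to PRL in si-CypB cells. IER3 (adjusted p = 0.0541) and UBALD2 (adjusted p = 0.0541) lost their calls without untreated replicate 3, IER3 also without PRL replicate 2, and SNORD68, SNX16 and RFC4 each without any of 4 single arrays (adjusted p up to 0.109). CEBPD and TNFRSF12A lost theirs without any single array but untreated replicate 2 (adjusted p up to 0.171), and with the replicate number as a block (adjusted p = 0.0761 and 0.073). The immediate early list passed again, with 4 of 35 higher and 0 lower (16 and 0 adjusted over the list alone; adjusted p = 1.53e-11), and held with an estimated correlation. Cholesterol genes had a median of 0.11 with 0 members called (8 rose and 0 fell adjusted over the list alone; adjusted p = 0.00202, and adjusted p = 0.254 with an estimated correlation). Without both arrays that stood apart the cholesterol median was 0.03, with 10 members higher and 0 lower (adjusted p = 0.0457). Interferon-stimulated genes had a median of -0.06 with 0 members called, and 0 adjusted over the list alone (adjusted p = 0.00202, and adjusted p = 0.833 with an estimated correlation).

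**Figure D4:**
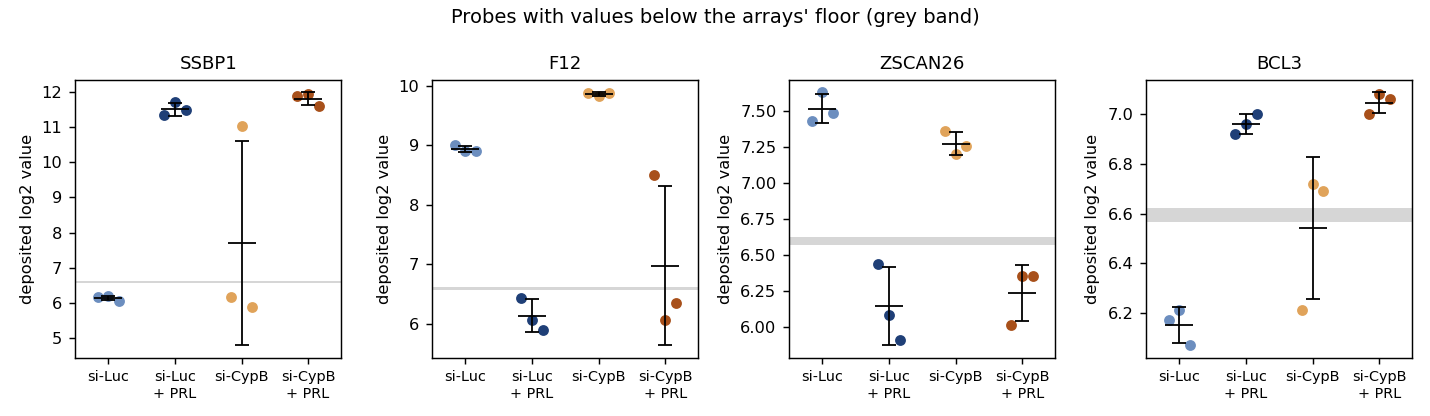
Log2 values of SSBP1, F12, ZSCAN26 and BCL3 on each of the 12 arrays, with the range of the arrays' floors, 6.57 to 6.62, as a grey band. SSBP1 lies below the band on 5 of 6 untreated arrays and above 11 on the PRL arrays.

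Averaged over both lines, 280 probes were called with PRL, 195 higher and 85 lower, for 155 and 75 genes. IER3 rose by 1.31, PHLDA1, a MAPK-induced gene, by 0.60, CEBPD and NABP1 by 0.60, CISH by 0.59 (adjusted p = 9.87e-07), KLF6 by 0.59, the MAPK phosphatase DUSP4 by 0.54 and MYC by 0.51 (adjusted p = 0.0315). PTPN1, a phosphatase of JAK2, rose by 0.25, the survival factor MCL1 by 0.38 and the death receptor TNFRSF10A by 0.23. BCL6 fell by 1.91 (adjusted p = 9.59e-12), VPS37D (-0.51), SMIM26 (-0.34), ALDH7A1 (-0.33) and RFC4 (-0.32) fell as well, and ESR1 fell by 0.15 (adjusted p = 0.0424).

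Of the immediate early list 8 of 35 rose and 0 fell (17 and 0 adjusted over the list alone; adjusted p = 1.01e-12), and the call held with an estimated correlation. Of 48 interferon-stimulated genes 1 fell, SP110 by 0.25, and 0 rose (5 and 1 adjusted over the list alone; adjusted p = 6.58e-05, and adjusted p = 0.505 with an estimated correlation). Among the 280 probes, 8 held values below the floor. The largest nominal rise, SSBP1 at 4.73, was read between 5.90 and 6.20 on 5 untreated arrays, at 11.03 on si-CypB replicate 2 and between 11.33 and 11.92 on PRL arrays. F12, nominally at -2.84, was read between 8.91 and 9.88 untreated and between 5.90 and 8.51 with PRL. Without si-CypB replicate 2 the count was 2195, and without si-Luc PRL replicate 1 it was 562. Leaving out each of the other arrays in turn gave between 96 and 208. Without si-Luc PRL replicate 3 the calls of MYC (adjusted p = 0.109), ESR1 (0.136), DUSP4 (0.129), PHLDA1 (0.0955), PTPN1 (0.0793), MCL1 (0.0718), VPS37D (0.0652), SP110 (0.15) and SSBP1 (0.0567) were lost. MYC, ESR1, DUSP4 and SP110 each lost the call without any of 10 single arrays, PHLDA1 without any of 9, MCL1 of 7, PTPN1 of 5, VPS37D of 3 and SSBP1 of 2.

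The PRL effects of the lines correlated at r = 0.612 across 18774 genes (Spearman's coefficient 0.377, covariance 0.00619), with no array shared and with r between 0.491 and 0.616 when single arrays were left out. CISH, IER3, KLF6 and YAP1 were higher in both, 4 genes against 0.0214 from independent lists, and BCL6 and ZSCAN26 were lower in both, against 0.00895. All 12 genes called in si-Luc had the same sign in si-CypB, and 83 of the 95 called in si-CypB had the same sign in si-Luc. ZSCAN26, read below the floor on 6 PRL arrays, and BCL3, below it on 4 untreated arrays, are among the 12. Their agreement is therefore uncertain. The r and the covariance also include SSBP1 and F12, which held values below the floor, and were not computed without these probes.

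The last comparison asked whether the PRL effect differed between the lines. limma's interaction test called 0 of 48701 probes, with 2378 at an unadjusted p under 0.05, and limma's treat also called 0. BCL6 came closest. Its fall was -2.14 in si-Luc and -1.69 in si-CypB cells, a difference of 0.46 (SE 0.05, adjusted p = 0.145). With PRL it read 7.57 to 7.64 on si-CypB arrays, nearer the floor than the 8.02 to 8.16 on si-Luc arrays. Compression near the floor may make the fall in si-CypB look smaller, so the difference is uncertain. CISH differed by 0.04 (adjusted p = 0.999), KLF6 did not pass (adjusted p = 0.916), and SQLE of sterol synthesis differed by 0.40 (adjusted p = 0.916). Without both arrays that stood apart, a setting chosen after the data were seen, 267 probes were called, 97 higher and 170 lower, and BCL6 differed by 0.41 (adjusted p = 0.014). Over all alternatives the adjusted p of BCL6 ran from 0.014 to 1.

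By camera, 4 lists passed in the interaction with 0 members called, and 0 adjusted over the list alone. The median difference was 0.14 for cholesterol genes (adjusted p = 0.000862, and adjusted p = 0.265 with an estimated correlation), 0.10 for hypoxia genes (adjusted p = 0.000862, and adjusted p = 0.265 with an estimated correlation), 0.05 for cell cycle genes (adjusted p = 0.00773, and adjusted p = 0.398 with an estimated correlation) and -0.04 for p53 targets (adjusted p = 0.0447, and adjusted p = 0.398 with an estimated correlation). No list held with an estimated correlation. In si-Luc cells, replicate 1 of the PRL arrays again lay apart, with a mean over hypoxia genes of 9.63 against 9.45 and 9.54 on its partners, and over cholesterol genes of 9.38 against 9.29 and 9.31. Without both arrays that stood apart the median was -0.08 for p53 targets, with 4 members lower and 1 higher (adjusted p = 0.00204), and 0.08 for cell cycle genes, with 1 higher and 0 lower (adjusted p = 0.0263).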

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

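The tests of si-CypB replicate 2 by position, by PPIB and by probes below the floor were chosen only after the results were seen. So were the tests of how probes below the floor divided the arrays and carried calls.

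Between the lines, the PRL effect on 4 gene lists differed by camera's interaction test, by a median of 0.141 for cholesterol genes, 0.103 for hypoxia genes, 0.049 for cell cycle genes and -0.04 for p53 targets, and each lost its call with an estimated correlation. The basal keratin KRT14 lay above the untreated mean on every PRL array of si-Luc and below it on every PRL array of si-CypB, with a difference of -0.147, and the T cell marker CD3D did the reverse, with 0.121. Both probes lay near the floor, and their interaction tests did not pass (adjusted p = 0.802 and 0.998).

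At 7 of the probes that held values below the floor, the untreated and PRL arrays parted, 4 of them low on untreated and 3 low on PRL arrays. Of 462 splits of the 12 arrays into 6 and 6, 1 had as many such probes, the treatment split itself, and the highest other split had 3. The splits were counted after the parting had been seen at these probes, so they describe it and are no separate test. Bead types missing from one set of arrays could give such a parting. That set may coincide with treatment, and treatment and such a set cannot be told apart here. Without the 12 probes below the floor 264 were called for the PRL average, against 280, but only 3 for PRL in si-Luc, against 16. Among dim probes 6.19% had an unadjusted p under 0.05 for PRL, against 4.75% for the line difference, which leaves open whether such a set reaches other probes.

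Replicate 2 of si-CypB stood apart from replicates 1 and 3, with r of 0.989 and 0.992 to them and of 0.994 to 0.996 to the si-CypB PRL arrays. Over 11 probes called for PRL in si-Luc its median position was 0.0764 (quartiles 0.0309 and 0.311) on a scale where 0 is the other si-CypB arrays and 1 the PRL ones, which argues against PRL-treated cells. Its PPIB value of 8.46 argues against si-Luc cells. Whether the array shares a set with the PRL arrays stays open. At the 7 probes below the floor where untreated and PRL arrays parted, it lay nearer the other untreated arrays at 5. It lay nearer the PRL arrays at 2, SSBP1 among them. Its deviation had an r of 0.299 with the PRL contrast in si-Luc over brighter probes and of 0.00583 over dim probes. Of the dim probes 4.72% had an unadjusted p under 0.05 for that contrast, about the share chance gives, so the r over dim probes decides nothing. No biological explanation was tested, and what sets the array apart stays open.

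Averaged over both treatments, 6566 probes differed between the lines. For these averages, log2 differences of expressed genes 10 places apart correlated at r = 0.00371, within shuffled gene order (highest 0.0279). At 20 places apart r was 0.0147, above most shuffles but below the highest, 0.0278. A correlation over all genes could miss a few long segments. In 619 windows of 40 expressed neighbours, however, 0 medians lay below -0.107 and 0 above 0.0918, limits set by shuffled gene order. This argues against gains or losses of chromosome segments that span such a window and shift its median past these limits. Smaller shifts stay open. Adjacent genes correlated at r = 0.0473, above all 1000 shuffles (highest 0.0255), so segments of few genes, or neighbours regulated together, stay open as well. Quantile normalisation again gave 6598 calls, but it moved almost nothing, so it says little of the authors' own normalisation. The silencing of PPIB, another effect of the vector, or other differences between the lines may each contribute, and with 1 line per vector they remain open.

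For counts of called probes, splits of 3 against 3 arrays number 10, too few for a share under 0.05. Untreated, 1 split gave as many as the real 4224 for the line difference, the real one itself, and the highest other gave 1. With PRL the real count was 4177 (1 split) and the highest other 0. For PRL in si-Luc the real count was 16 (1 split) and the highest other 0. For PRL in si-CypB it was 125, and 2 splits gave as many, since the split of replicates 1 and 3 with PRL replicate 3 against the rest called 464, which points to a structure of these samples. That split kept both arrays numbered 3 together and both numbered 2 together. It also placed si-CypB replicate 2, the array that stood apart, with PRL replicates 1 and 2. Besides the real split, those that part every pair of equal numbers called 0. For the averages over 4 groups, 100 splits were drawn. Only 1, the real one itself, reached the 6566 of the line difference (highest other 2), and likewise 1 the 280 of PRL (highest other 8). This makes a chance division of these arrays unlikely for both. The splits treat the arrays as independent, and for PRL an array set that coincides with treatment would give the same outcome. For the interaction the real count was 0, which all 100 splits reach by construction, so the splits say nothing of chance there, and the highest other called 326.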

How the results depend on the processing

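The fits without both arrays that stood apart, without probes below the floor and without PPIB among the cyclophilins were chosen only after the results were seen. Over all alternatives, 7121 values of named genes stayed on their side of the threshold, 421 lost the call and 67 gained it. Of values called in the main fit or the alternative, 0 reversed. Values called in neither were counted as staying whatever their sign. Testing against a fold of 1.2 left 653, 686, 4 and 3 probes for the line difference untreated, with PRL, and PRL in si-Luc and si-CypB, and 1070 and 7 for the averages of line and PRL. The main fit shares a spread per probe over all groups. Over brighter probes the residual SD ran from 0.041 to 0.046 on untreated si-Luc arrays and from 0.040 to 0.082 with PRL. On si-CypB arrays it ran from 0.066 to 0.134 untreated and from 0.053 to 0.062 with PRL. With only the groups compared in the fit, PRL called 293 in si-Luc and 6 in si-CypB, the reverse order of the main fit. Array weights gave 100 and 216, and 644 for the PRL average. PRL in si-Luc called 3 with bright probes only, 4 with leading probes only and 3 without probes below the floor. Without both arrays that stood apart, PRL called 841 in si-Luc, 2549 in si-CypB and 2964 on average, the interaction 267, and 5 lists passed for the PRL average. With an estimated correlation, lists past the threshold fell to 6, 6, 1 and 1 for the 2-group contrasts in the same order, 0 for the interaction and 1 for the PRL average. Apart from the smaller sets tested, the cause of these shifts was not tested. BCL6, CISH and IER3 kept their calls for PRL in si-Luc under every alternative. No list median of a line difference changed sign under another scaling, but centring moved the arrays by at most 0.00719, so this says little. List medians turned sign for 2 lists for PRL in si-Luc, 1 in si-CypB, 2 in the interaction and 5 for the PRL average. Their main medians were at most 0.014 in size.

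Leaving out each array in turn gave 3012 to 4445 probes for the line difference untreated, 2941 to 4103 with PRL, 5724 to 7133 averaged, 7 to 137 for PRL in si-Luc (137 without si-Luc PRL replicate 1), 40 to 1934 in si-CypB (1934 without si-CypB replicate 2), 96 to 2195 for the PRL average and 0 for the interaction. The interaction called 0 by limma under every alternative fixed in advance. The share of PRL calls in si-Luc that were higher, 62.5%, was 46.2% after quantile normalisation again. Signal over background limits the probes near the floor, whose differences are compressed.

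With the replicate number as a block the counts were 4327, 4357, 23 and 140 for the 2-group contrasts in the order above, 0 for the interaction, and 6665 and 347 for the averages. For PRL in si-CypB, where the numbers were taken to pair the arrays, CEBPD and TNFRSF12A lost their calls. There UGCG gained one (adjusted p = 0.0176), and no other named gene or list changed. In the other comparisons the numbers were not treated as pairing the arrays. Over all 12 pairs of groups and numbers, those of si-CypB included, 7 correlated above 0.1, with r from -0.179 to 0.466, and 7 correlated best with their own number. Between untreated and PRL arrays of si-Luc cells r was 0.294, 0.266 and 0.024, each best with its own number, so pairing there stays open. Under the block KLF6 (adjusted p = 0.054), YAP1 (0.054), ALDH7A1 (0.05) and TMEM230 (0.0662) were not called for PRL in si-Luc, nor ESR1 (0.0548) and SP110 (0.0683) for the PRL average. Of the lists, 4 passed for PRL in si-Luc under it, against 6, without STAT5 targets (adjusted p = 0.0703) and apoptosis regulators (adjusted p = 0.0523), and the hormone and growth factor list passed for the line difference untreated (adjusted p = 0.0474).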

Other observations

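These groups were chosen after their values were seen. FKBP proteins are the other large family of immunophilins, and the members named here did not all move one way in the si-CypB line. The family was not tested as a list. FKBP5, a cochaperone of steroid receptors and a target of glucocorticoid and progesterone receptors, was lower by -1.26 untreated (adjusted p = 2.07e-07) and by -1.23 with PRL. FKBP4, its relative on the same receptor complexes, was higher by 0.64 (adjusted p = 0.00344) and 0.79, and FKBP3 by 0.29 and 0.47. FKBP14, a collagen folding partner, was lower by -0.42 untreated, and FKBP1A did not pass (0.23, adjusted p = 0.754).

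Other small RNAs were read beside those with the largest rises. BC200, the product of BCYRN1, and SNAR-A1 are transcribed by RNA polymerase III, as are RN7SK and RPPH1, which lay near the floor and differed by 0.04 (adjusted p = 0.721) and 0.17 (adjusted p = 0.12) between the untreated lines. SNAR-C3, SNAR-E and SNAR-G1 read close to the floor in all groups, where a change could not show. SNORD68, a small nucleolar RNA, was higher by 0.61 untreated (adjusted p = 7.72e-05) and differed by 0.13 with PRL (adjusted p = 0.323). Among metallothioneins, MT2A was higher by 1.52 and MT1F by 0.51 (adjusted p = 0.000153), while MT1G read near the floor and differed by 0.05 (adjusted p = 0.409). Other members are not given here, and the family was not tested as a list.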
